A study of Mus musculus with 12 samples.

How the data were processed

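RNA of neural stem cells sorted from the subventricular zone of adult male C57B6J mice was measured on Affymetrix MOE 430 2.0 arrays. Per the labels' protocols, total RNA was transcribed and amplified with the NuGEN Ovation Pico whole transcriptome system, a method for small amounts of RNA, and labelled with biotin. The labels describe 12 samples, 4 in each of 3 groups: quiescent, quiescent 48 h after irradiation, and activated. The radiation dose, the surface markers used for sorting and the number of animals per sample are not given in the sources used here. Samples were grouped by the state named in their labels. Quiescent replicate 3 and activated replicate 4 had no values in the table used and were not analysed here, which leaves 3, 4 and 3 arrays.

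The deposited table holds 1 intensity per probe set and array on a linear scale, as whole numbers from 3 to 34883. The software and method by which the authors made these intensities from the scans are not given in the sources used here. Medians were 6 or 7 on each array, among the lowest values, so they say little about scale. The 75th percentiles lay between 83 and 104, a broadly similar scale as deposited. Low values pile up between about 4 and 10 with no spread beneath, which means that the deposited intensity of a weak transcript carries little information. An intensity of at most 10 is called near the lower limit here. Of the 18193 genes, 5775 (31.7%) were near the lower limit on all 10 arrays. Scan dates were not used here, so scan batches could not be tested.

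Of the 45037 probe sets, 34945 had exactly 1 gene symbol in the platform annotation, 932 had several and 9160 had none. Of the former, 34741 were matched by Entrez identifier to the RefSeq gene table of the GRCm38.p6 assembly, used for names only, and no symbol needed an update. No coordinates are given because the array values come with no genome build. Each gene was represented by its probe set with the highest mean over all arrays, and 9010 genes had several. Genes without a probe set of their own name, 1 of the genes fixed in advance among them, were not analysed here.

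Intensities were transformed as log2(intensity + 16) with no further normalization and no filter. Groups were compared with limma (version 3.58.1, R 4.3.3): lmFit with a mean per group over all 10 arrays, which share 1 estimate of the spread per gene (7 residual degrees of freedom), and eBayes moderation, two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. The design had been written for 12 arrays. With 10, the fit has 7 residual degrees of freedom, and the quiescent arrays were divided 1 against 2 (6 assignments) where differences had to share no array. The prior of the moderation was weak (0.422 degrees of freedom), so each gene's own spread dominated its test.

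Gene lists (34 in all) were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives. The lists cover the cell cycle, stem cell and neuroblast markers, markers of other cell types of the region, p53 targets, DNA repair, interferon and inflammatory genes, reactive astrocytes, adhesion, Notch and BMP signalling, metabolism, protein synthesis and turnover, immediate early genes and apoptosis. They were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 34 lists and 3 comparisons, and again with an estimated correlation and with fry. Camera sets a list against all other genes. Fry asks whether a list's members move one way on balance, or in either direction in its mixed form. Genes called are counted over all genes and adjusted over the list alone.

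The rule for named genes took 3 kinds of genes per comparison: the 8 largest rises and 8 largest falls among called genes whose arrays of one group all lay above those of the other; up to 3 members with the smallest adjusted p from each list called in that comparison; and a fixed set of markers given whether or not they changed. Unnamed probe sets and predicted genes were left out. Part of these genes are given in the text, 79, 37 and 75 in the 3 comparisons being eligible. Arrays of both groups were fully separated for 3516 genes between activated and quiescent cells, where chance gives 10% of genes for 3 arrays against 3.

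The shift of irradiated cells along the quiescent to activated axis was measured as the slope of the irradiated minus quiescent log2 differences on the activated minus quiescent log2 differences, with the variance of the latter corrected for its estimated noise. Array scores on the axis were compared by a permutation test over all 35 splits, called exact because every split was counted. Each quiescent array was scored against the other quiescent arrays, and each irradiated array as a mean over such baselines. The scores were not rebuilt for each split, so they are not fully exchangeable and these p-values are approximate. Overlaps with shared quiescent arrays were set beside simulated groups without an effect (50 runs).

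The steps were tested on simulated data with the real group means and normal noise of each gene's residual SD. With 200 of 18193 genes changed in each of 5 runs, the fit recovered, between irradiated and quiescent groups, 2% of 2-fold, 8% of 4-fold, 22% of 8-fold and 32.8% of 16-fold changes, and 10.5% of its calls were false. Between activated and quiescent groups it recovered 1.2%, 4.8%, 17.2% and 28% (9.86% false), and between activated and irradiated groups 2.8%, 9.6%, 19.6% and 30% (4.91% false). Changes were planted only in genes well above the lower limit in the reference group, so these shares do not describe genes that rise from that limit. Among the brighter genes, many true changes of single genes are thus missed by a design of this size. A list planted between activated and quiescent groups was called in 5 of 5 runs. No list was called between irradiated and quiescent groups, where none was planted, and other lists in the planted comparison were not counted. Simulated noise was independent between genes, so these runs do not test lists whose members vary together. A planted axis slope of 0.2 was recovered as 0.199.

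Alternatives were quantile normalization, median centring, leaving out the dimmest 25% or 50% of the genes, a pseudocount of 1, the mean of all probe sets of a gene, every probe set, limma with trend and robust moderation, array weights, a fit of only the 2 groups compared, the replicate number as a block, a stricter threshold (0.01), a minimum change of 2-fold and leaving out each array in turn. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures with matplotlib 3.10.9.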

Results

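Neural stem cells of the adult mouse subventricular zone, the germinal layer along the lateral ventricles that supplies new neurons to the olfactory bulb, were sorted freshly from male C57B6J mice in 3 states. The states were quiescent cells, quiescent cells taken 48 h after irradiation, and activated cells. Each of the 12 samples described was hybridised to an Affymetrix MOE 430 2.0 array, a 3'-biased short-oligonucleotide array with several probe sets for many genes. Values of 10 arrays were analysed here: 3 quiescent (replicates 1, 2 and 4), 4 irradiated quiescent (replicates 1 to 4) and 3 activated (replicates 1 to 3). The number of arrays limits the precision of every difference below. Nothing in the labels says whether replicates came from separate animals. P-values of single genes thus measure only the spread between these samples, which may be technical. Camera p-values of lists rest on the spread across genes as well. Fisher's exact tests of gene families count genes as units. Genes are not independent replicates.

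On each array between 56.6% and 59.2% of the probe sets lay at or below an intensity of 10, close to the lower limit of the deposited values. Over the 18193 genes, activated arrays correlated with each other at r = 0.87 to 0.92 and quiescent arrays at 0.85 to 0.86. Irradiated arrays correlated with each other at 0.83 to 0.87 and with quiescent arrays at 0.82 to 0.88, while activated arrays correlated with quiescent arrays at 0.72 to 0.78. These correlations are across genes, which are not independent replicates. Intensities below are means ± SD of the deposited values. Log2 differences are on the log2(intensity + 16) scale ± SE from the limma fit, and this scale understates the change of genes near the lower limit in one group. For a gene near that limit in a group, the value there is background rather than a level.

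Activated and quiescent cells were compared to find which transcripts separate the 2 states. Genes of cell division were the group that differed most. Of the 52 measured mitosis genes, 47 rose in activated cells and 5 did not pass the test, and the median log2 difference was 4.99 (adjusted p = 5.29e-79). With an estimated correlation in camera the adjusted p of this list was 0.00177. Adjusted p of a list is with the preset correlation unless stated. Ube2c, which loads ubiquitin for the anaphase-promoting complex, had an intensity of 9779.7 ± 1396 in activated cells (SD, n = 3) and 7 ± 1.73 in quiescent cells (SD, n = 3). Mki67, the proliferation antigen, stood at 10428 ± 802 against 83.3 ± 74.7, a log2 difference of 7.08 ± 0.58 (adjusted p = 5.12e-04). Top2a, the topoisomerase of dividing cells, and Ccna2, which encodes cyclin A2, both rose by a log2 difference of 6.98, with SE of 0.39 and 0.41. Cdca8 and Aurkb of the chromosomal passenger complex rose by 7.94 and 5.99, and Pbk, Aspm, Cenpf and Cdca3 by 7.21, 7.13, 6.70 and 6.03. Of 41 S phase and replication genes, 23 rose and 18 did not pass (adjusted p = 3.51e-32). Among them were Mcm5 of the replicative helicase (6.69 ± 0.09), the uracil-DNA glycosylase gene Ung (6.58 ± 0.27) and Chaf1b of the chromatin assembly factor (3.58 ± 0.13). Adjusted over the list alone, 50 mitosis genes and 34 S phase genes rose.

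The lists of repair genes were also called higher, though most of their members did not pass. In the list of homologous recombination and Fanconi genes, 5 of 30 rose, 11 adjusted over the list alone, and none fell (adjusted p = 5.91e-11). Brca1 stood at 837 ± 451 in activated cells and 6.33 ± 0.577 in quiescent cells, and Fancd2 and Clspn rose by 2.21 and 4.24. In the list of end joining and damage sensing genes, 4 of 21 rose, 5 adjusted over the list alone (adjusted p = 4.31e-06). Its members with the smallest adjusted p were Mdc1, a scaffold at DNA breaks (4.61 ± 0.56), the histone gene H2ax (3.85 ± 0.67) and Parp2 (2.97 ± 0.61). The call of H2ax was lost without any one of 4 arrays (highest adjusted p 0.0582, without quiescent replicate 4), and that of Parp2 without any one of 6 (0.101, without quiescent replicate 4).

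Genes of protein synthesis were also higher in activated cells. Of 41 ribosomal protein genes, 22 rose and 19 did not pass, and 32 rose adjusted over the list alone (median log2 difference 1.66, adjusted p = 7.47e-24). Rpl11 went from 2151 ± 495 to 9259.7 ± 697, Rps19 rose by 3.17 and Rps7 by 1.97. Of 41 ribosome biogenesis genes, 6 rose, 8 adjusted over the list alone (adjusted p = 4.93e-10), among them the nucleolar genes Ncl (2.38 ± 0.20), Npm1 (2.66 ± 0.24) and Nop58 (5.90 ± 0.91). Of 34 proteasome and chaperone genes, 4 rose, 8 adjusted over the list alone (adjusted p = 2.30e-07). The mitochondrial chaperone gene Hspa9 rose by 0.95, Hsp90aa1 by 1.71 and the chaperonin subunit gene Cct6a by 2.11. Without activated replicate 2 the adjusted p was 0.0704 for Hsp90aa1 and 0.102 for Cct6a, and leaving out 1 of 4 or 5 other arrays also ended these calls. The Hspa9 call was lost with the mean of its probe sets (log2 difference 0.43, adjusted p = 0.138), without the dimmest 50% of genes (0.160) and with only the 2 groups in the fit (0.0714).

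Astroglial transcripts fell. Of 42 astroglial and quiescent stem cell markers, 32 fell in activated cells, 10 did not pass and none rose (median log2 difference -2.78, adjusted p = 1.90e-41), with 37 lower adjusted over the list alone. Lcat, a lipoprotein-modifying acyltransferase, stood at 3028 ± 672 in quiescent and 7.67 ± 2.89 in activated cells. The glutamate transporter gene Slc1a3 fell from 14853 ± 2402 to 3152 ± 804 (log2 difference -2.25 ± 0.21, adjusted p = 8.85e-04). The adhesion molecule gene Vcam1 differed by -3.35 ± 0.17 and Glul, the glutamine synthetase gene, by -1.29 ± 0.07, a call lost without the dimmest 50% of genes (adjusted p = 0.0571). Of 71 cell adhesion and extracellular matrix genes, 24 fell, 27 adjusted over the list alone, and none rose (adjusted p = 1.23e-12), including Sparcl1 (-3.61 ± 0.24) and the protease inhibitor gene Timp3 (-3.63 ± 0.25). Other steep falls were in Septin4 (-6.89), the growth factor gene Gdf10 (-6.60), Mfap3l (-6.55), the GABA receptor subunit gene Gabrb1 (-6.09), Tmem88b (-5.91) and the calcium channel subunit gene Cacna2d2 (-5.85). The call of Cacna2d2 was lost without any one of 7 arrays, with a highest adjusted p of 0.0981 without quiescent replicate 1, and that of Gabrb1 with only the 2 groups in the fit (adjusted p = 0.0510).

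Catabolic and lipid genes fell as well. Of 32 fatty acid oxidation genes, 6 fell and 2 rose (adjusted p = 5.39e-06), 9 and 2 adjusted over the list alone. The 3 members with the smallest adjusted p, Acsbg1 (-4.14 ± 0.26), Acsl6 (-3.93 ± 0.29) and Acsl3 (-2.71 ± 0.28), encode acyl-CoA synthetases, which activate fatty acids for synthesis of complex lipids as well as for oxidation. Of 20 cholesterol synthesis genes, 4 fell, by both adjustments (adjusted p = 3.31e-04): Msmo1 differed by -3.14 ± 0.34, Dhcr7 by -1.93 ± 0.34 and Hmgcs1 by -0.73 ± 0.13. The Msmo1 call was lost with the mean of its probe sets (log2 difference -2.33, adjusted p = 0.139). Each of the last 2 calls was lost without any one of 3 or 4 arrays, with the highest adjusted p (0.0632 and 0.0734) without activated replicate 2. Of 22 glycolysis genes, 6 fell (adjusted p = 1.22e-06), among them Aldoc, Ldhb and Pfkp at -2.51, -1.19 (call lost without the dimmest 50% of genes, adjusted p = 0.0789) and -4.16, and adjusted over the list alone 8 fell and 1 rose. Of 30 lysosome and autophagy genes, 9 fell, 18 adjusted over the list alone (adjusted p = 1.64e-12), including Lamp2 (-2.07 ± 0.16), Psap (-2.79 ± 0.24) and Lamp1 (-1.56 ± 0.18).

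Progenitor and neuroblast transcripts were higher in activated cells. Of 36 activated stem cell and transit amplifying markers, 16 rose, 2 fell and 18 did not pass (adjusted p = 2.55e-10), with 22 higher and 3 lower adjusted over the list alone. Dlx1, an interneuron lineage factor, went from 6.33 ± 0.577 to 2187 ± 943 and Cdk6 rose by 5.34, whereas the oligodendrocyte lineage factor gene Olig1 fell, with a log2 difference of -2.24. Of 30 neuroblast markers, 6 rose and 1 fell, 10 and 2 adjusted over the list alone. The list was called (adjusted p = 3.95e-05) but not with an estimated correlation (adjusted p = 0.0514 with an estimated correlation). Cd24a, a surface antigen used to sort neuroblasts, went from 30.7 ± 41.0 to 3223 ± 1299 (log2 difference 6.38 ± 0.56), and Sox4 and the neuronal RNA-binding gene Elavl4 rose by 5.27 and 3.85. Nes, the intermediate filament of neural progenitors, rose by 2.98 ± 0.27 to an intensity of 182 ± 88.2. Dcx, a microtubule protein of migrating neuroblasts, was higher by 3.39 ± 0.79 and just missed the threshold (adjusted p = 0.0508). Egfr, the receptor that marks activated cells in this niche, stood at 4261 ± 813 against 1503 ± 914 and did not pass (log2 difference 1.66 ± 0.64, adjusted p = 0.246).

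The other genes given whether or not they changed did not pass. Gfap differed by -0.35 ± 1.35, Prom1 by -1.86 ± 0.80, Sox2 by -0.54 ± 0.27 and the cell cycle inhibitor gene Cdkn1a by 2.08 ± 0.93, with adjusted p from 0.316 for Prom1 to 1.00 for Gfap. The probe set used for Fut4 was near the lower limit on every array. Immediate early and dissociation genes were called as a list (adjusted p = 4.97e-04) but not with an estimated correlation (adjusted p = 0.123 with an estimated correlation): 7 of 26 rose and 1 fell, 8 and 1 adjusted over the list alone. Ier2 and the stress-responsive factor gene Atf3 rose by 2.75 and 1.44, to intensities of 166 ± 64.5 and 42.0 ± 13.2. The matricellular gene Ccn1 fell (log2 difference -3.96 ± 0.21), a call lost when all its probe sets were averaged.

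Oligodendrocyte, neuron and endothelial markers were called lower in activated cells, none of them with an estimated correlation, and Ttr fell. Ttr, the transthyretin gene that is the leading transcript of the choroid plexus, had the largest drop of all, from 15076 ± 3776 in quiescent cells (SD, n = 3) to 6 on each activated array, and it stood at 14804 on average in irradiated cells. No other of the 12 choroid plexus markers exceeded 100 on more than 2 of the 10 arrays, and the list was not called (adjusted p = 0.120). Of 18 genes in the myelinating oligodendrocyte list, 7 fell in activated cells and 11 did not pass, and 11 fell adjusted over the list alone. The list was called (adjusted p = 3.69e-10, and adjusted p = 0.0625 with an estimated correlation). Among the genes that did not pass was Trh, a different gene taken by synonym for the listed Trf, at a mean of 5 in each group. Cnp went from 9543 ± 1476 to 1277 ± 209.9, Ermn differed by -4.75 ± 0.57 and Cldn11 by -4.03 ± 0.70, and the Cldn11 call was lost without quiescent replicate 2 (adjusted p = 0.0596), without activated replicate 1 (0.0543) and with only the 2 groups in the fit (0.116). Mature neuron markers were called lower (adjusted p = 0.00334; adjusted p = 0.398 with an estimated correlation), with 1 of 20 members passing, Syt1 (-2.96 ± 0.68), and none adjusted over the list alone. The Syt1 call was lost without any one of 8 arrays (highest adjusted p 0.143, without activated replicate 2). Penk stood at 5160 on quiescent replicate 1 and at 1123 and 280 on the other quiescent arrays, and Penk and Ppp1r1b did not pass. Endothelial markers were called lower (adjusted p = 0.0168; adjusted p = 0.326 with an estimated correlation). Of its 23 members only the glucose transporter gene Slc2a1 passed (-2.25 ± 0.29), by both adjustments, while Emcn and Esam did not. The neuron list was not called without quiescent replicate 1 (adjusted p = 0.184). The endothelial list was not called without quiescent replicate 1 (0.0684), quiescent replicate 2 (0.0747), activated replicate 1 (0.0767) or activated replicate 2 (0.0502).

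Besides choroid plexus markers, 14 of the 34 lists were not called. Adjusted p was 0.0527 for oligodendrocyte precursor markers, 0.0530 for pericyte and fibroblast markers, 0.148 for cyclin-dependent kinase inhibitors and G0 genes and 0.253 for the BMP and TGF-beta pathway. It was 0.407 for the Notch pathway, 0.444 for inflammatory and NF-kB genes, 0.469 for apoptosis genes, 0.527 for erythroid genes and 0.549 for the interferon response. Microglia and macrophage markers (0.581), p53 target genes (0.633), oxidative phosphorylation (0.719), ependymal markers (0.803) and reactive astrocyte genes (0.969) were further from the threshold. Over all genes, 1094 of 18193 passed an adjusted p of 0.05, 526 of them higher and 568 lower in activated cells, and 2942 had an unadjusted p under 0.05. The count was 773 to 1036 without each array in turn, and 806 without quiescent replicate 1, which has the highest neuronal transcripts. Of the 19 lists called, 14 were also called with an estimated correlation. Their adjusted p in camera then ran only from 1.34e-04 (S phase and replication) to 0.0366 (cholesterol synthesis). The 5 that were not called so are the neuroblast, mature neuron, oligodendrocyte, endothelial and immediate early lists.

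**Figure D1:**
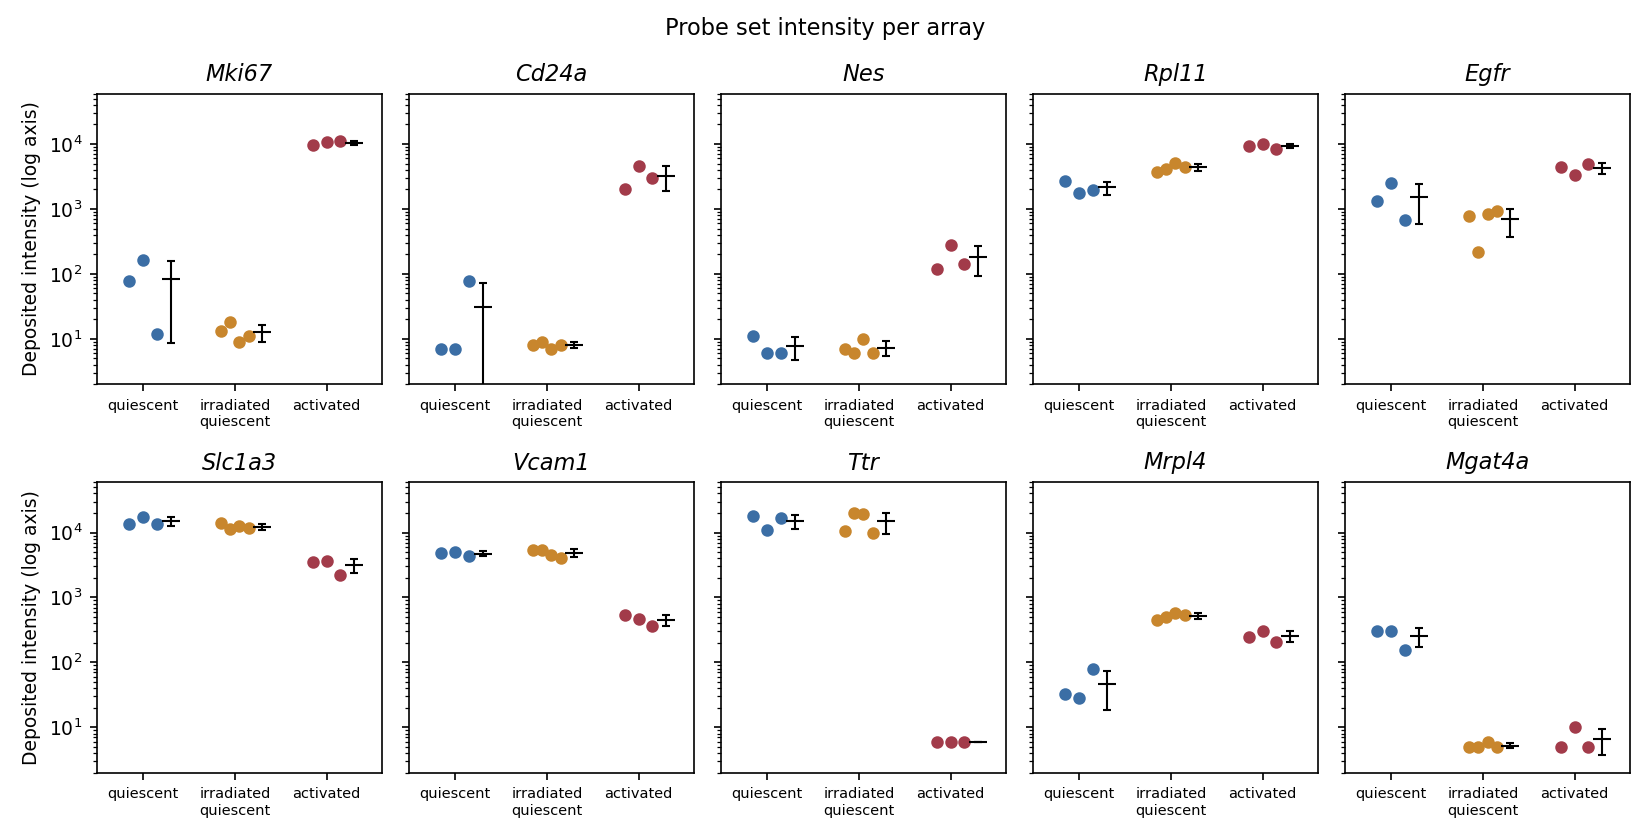
Deposited probe set intensity (log axis) of 10 genes on each array, by group. Each point is 1 array, and the black marks are the group mean ± SD (n = 3 quiescent, 4 irradiated quiescent and 3 activated), with bars that would pass below the axis ended there. Mki67 and Cd24a stand far higher in the activated arrays, Slc1a3, Vcam1 and Ttr far lower, and Mrpl4 and Mgat4a are the 2 genes that passed between irradiated and quiescent arrays.

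Irradiated and unirradiated quiescent cells were compared to find what remained different 48 h after irradiation. Few single genes separated them. Mrpl4, which encodes a protein of the large mitochondrial ribosomal subunit, rose from 46.7 ± 28.1 (SD, n = 3) to 518 ± 55.6 (SD, n = 4), a log2 difference of 3.17 ± 0.27 (adjusted p = 0.0454). Mgat4a, a glycosyltransferase gene of N-glycan branching, fell from 255 ± 85.2 to 5.25 ± 0.500, at the lower limit (log2 difference -3.62 ± 0.22, adjusted p = 0.00664). These were the only genes among 18193 that passed in the limma fit. An unadjusted p under 0.05 was found for 720 (3.96%), where uniform p-values would give about 910. Other splits of the quiescent and irradiated arrays gave 616 to 1038 such genes, so 720 lies within their range. The number that passed was 44 without quiescent replicate 4, 17 without quiescent replicate 1 and 12 without quiescent replicate 2. It was 3 without irradiated replicate 4, 1 without activated replicate 2 or activated replicate 3, and 0 without irradiated replicate 1 or irradiated replicate 2. The Mrpl4 call was lost without any one of 7 arrays (highest adjusted p 0.242, without irradiated replicate 1) and the Mgat4a call without irradiated replicate 1 or 2 (highest 0.0693). Mrpl4 also lost its call under quantile normalization (adjusted p = 0.115), without the dimmest 50% of genes (0.0747), with trend and robust moderation (0.0541), with array weights (0.0624) and with only the 2 groups in the fit (0.221). Mgat4a lost its call with the mean of its probe sets (0.0720) and with only the 2 groups (0.113).

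Interferon response genes were higher as a group after irradiation. The list of 35 was called (mean log2 difference 0.44, adjusted p = 0.00524), and it was the only list of this comparison also called with an estimated correlation (adjusted p = 0.0387 with an estimated correlation). Both values are adjusted over the lists of all 3 comparisons, and within this comparison alone no list was called with an estimated correlation. No member passed over all genes or adjusted over the list alone. Ifit2 stood at 94.5 ± 65.3 in irradiated and 7.67 ± 2.89 in quiescent cells, Oasl2 at 149 ± 163 and 8 ± 5.20, and the MHC class I light chain gene B2m at 3498 ± 569.8 and 2184 ± 885. The mean of the list was higher on each of the 4 irradiated arrays, at 5.92 to 6.18, than on any of the 3 quiescent arrays, at 5.43 to 5.76 (log2). Irradiated replicate 4 had the highest value, and without it the list was not called (adjusted p = 0.0761).

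Targets of p53, the factor activated by DNA damage, did not pass as a list. Of the 41 members none passed by either adjustment, and the mean log2 difference was 0.29 (adjusted p = 0.163). The fry test, which asks only whether members move one way on balance, gave an adjusted p of 0.0241 in the higher direction. Fry also called this list higher in activated than in quiescent cells (adjusted p = 1.43e-04) and than in irradiated cells (adjusted p = 0.00139). A fry call of this list was thus not particular to irradiation. The mean of the list was 6.46 to 6.78 on the 4 irradiated arrays and 6.19 to 6.42 on the 3 quiescent arrays (log2). Cdkn1a, the cell cycle inhibitor gene induced by p53, stood at 36, 95, 459 and 172 on the irradiated arrays and at 40, 20 and 30 on the quiescent arrays (log2 difference 1.74 ± 0.87, adjusted p = 0.970).

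Fatty acid oxidation, oxidative phosphorylation and ribosomal protein genes were higher as lists after irradiation, but not with an estimated correlation. Fatty acid oxidation was called at an adjusted p of 0.00683 (adjusted p = 0.164 with an estimated correlation), with 3 of 32 members higher adjusted over the list alone and none over all genes. Hadha, a subunit of the mitochondrial trifunctional protein, stood at 2352 ± 342 in irradiated and 727 ± 258 in quiescent cells, Ppara at 439.5 ± 217 and 63.0 ± 52.1, and Acot1 at 1125 ± 328 and 446 ± 152. Oxidative phosphorylation was called at 0.00241 (adjusted p = 0.389 with an estimated correlation), with none of 39 members passing by either adjustment. Its leading members Ndufa9, Ndufa4 and Uqcrq differed by 1.34 ± 0.32, 0.77 ± 0.32 and 0.62 ± 0.26. Ribosomal proteins were called at 1.87e-04 (adjusted p = 0.287 with an estimated correlation), with 1 of 41 members higher adjusted over the list alone, Rpl11 (1.03 ± 0.16), while Rps20 differed by 1.04 ± 0.34 and Rps7 lay the other way (-0.77 ± 0.19). Without quiescent replicate 2 neither oxidative phosphorylation (adjusted p = 0.627) nor ribosomal proteins (adjusted p = 0.388) was called.

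Immediate early genes and markers of 3 other cell classes were lower as lists, again not with an estimated correlation. Immediate early and dissociation genes had an adjusted p of 2.46e-05 (adjusted p = 0.0673 with an estimated correlation). Fos, a first-wave response gene, stood at 58.0 ± 19.6 against 333 ± 253, Klf6 at 514 ± 252 against 1539.7 ± 696, and the heat shock gene Hspa1a at 7.50 ± 3 against 126 ± 109. The mean of the list was 7.46 and 7.31 on quiescent replicates 1 and 2, but 6.61 on quiescent replicate 4, beside 6.39 to 6.57 on the irradiated arrays (log2), and Hspa1a was at 152, 219 and 6 on these quiescent arrays. Endothelial markers had an adjusted p of 1.43e-04 (adjusted p = 0.148 with an estimated correlation), and Abcb1a, Emcn and Esam differed by -2.17, -0.88 and -1.90. Esam was at 241 and 73 on quiescent replicates 1 and 2 and at 5 on quiescent replicate 4 and each irradiated array. Mature neuron markers had an adjusted p of 0.00110 (adjusted p = 0.348 with an estimated correlation), with Syt1, Penk and Camk2a at -2.19, -3.34 and -2.69, and the list was not called without quiescent replicate 1 (adjusted p = 0.882). Neuroblast markers had an adjusted p of 0.00237 (adjusted p = 0.125 with an estimated correlation), with Map1b, Stmn1 and Runx1t1 at -2.57, -0.75 and -1.65, and the mean of the list on quiescent replicate 4 (6.10) lay below that on irradiated replicate 4 (6.23). No member of these 4 lists passed by either adjustment.

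Cell cycle, repair and stem cell lists were not called after irradiation. Adjusted p was 0.340 for mitosis, 0.678 for S phase and replication, 0.678 for homologous recombination and Fanconi genes and 0.944 for end joining and damage sensing genes. Astroglial and quiescent stem cell markers had 0.510 and activated stem cell and transit amplifying markers 0.157. The other 20 uncalled lists, apoptosis, inflammatory and reactive astrocyte genes among them, had adjusted p of at least 0.0644, the value for pericyte and fibroblast markers. No member of any of these 26 lists passed over all genes, and adjusted over the list alone 1 passed in each of 3: higher in ribosome biogenesis, lower in oligodendrocyte precursor markers and in lysosome and autophagy. Mki67 stood at 12.8 ± 3.86 in irradiated cells, and Egfr at 694 ± 322, Gfap at 786 ± 1093, Prom1 at 443 ± 269, Sox2 at 2594 ± 618 and Slc1a3 at 12368 ± 1258 (SD, n = 4). None of these, nor Cd24a, Dcx, Nes or Fut4, passed against quiescent cells (adjusted p of at least 0.970 for each).

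**Figure D2:**
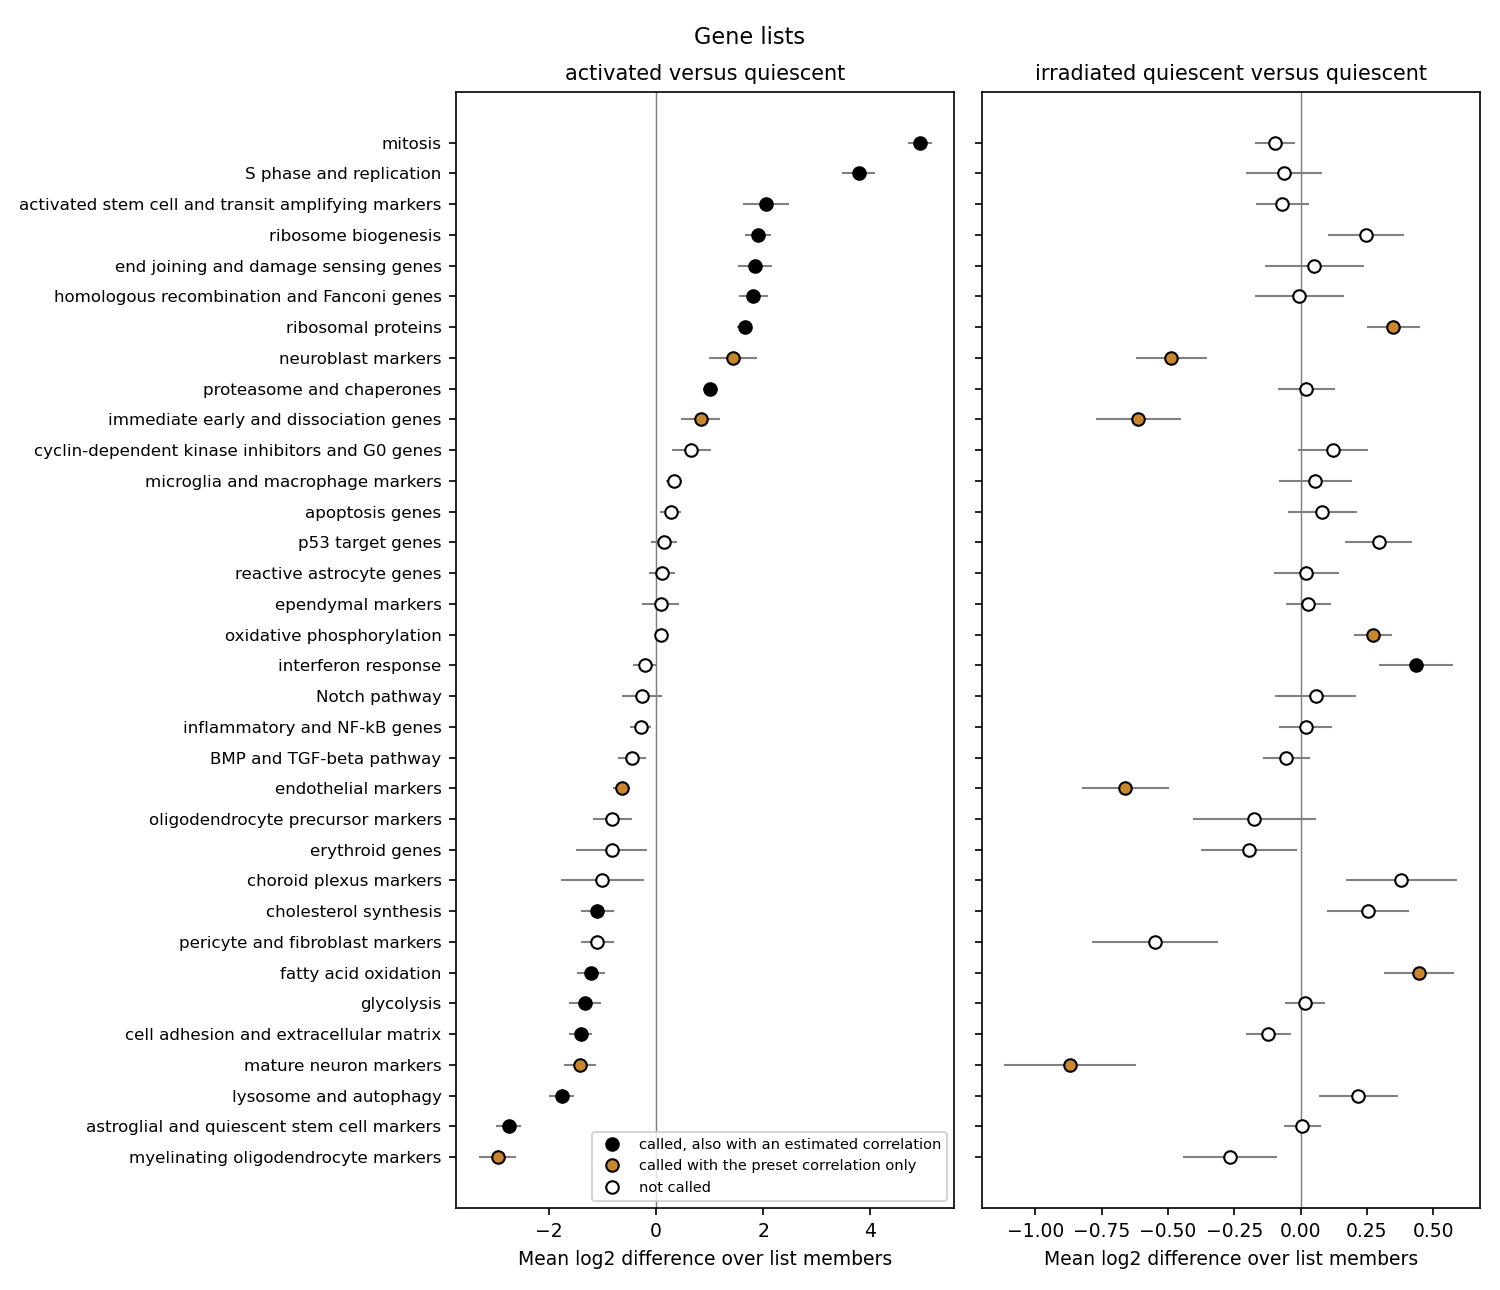
Mean log2 difference over the members of each of the 34 gene lists, for activated minus quiescent (left) and irradiated quiescent minus quiescent (right, on a narrower axis). Horizontal bars are the SE of the mean over members, which are not independent, and fill shows whether the list test called the list. Mitosis (52 genes) leads on the left, and on the right only the interferon response is called with both correlations.

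**Figure D3:**
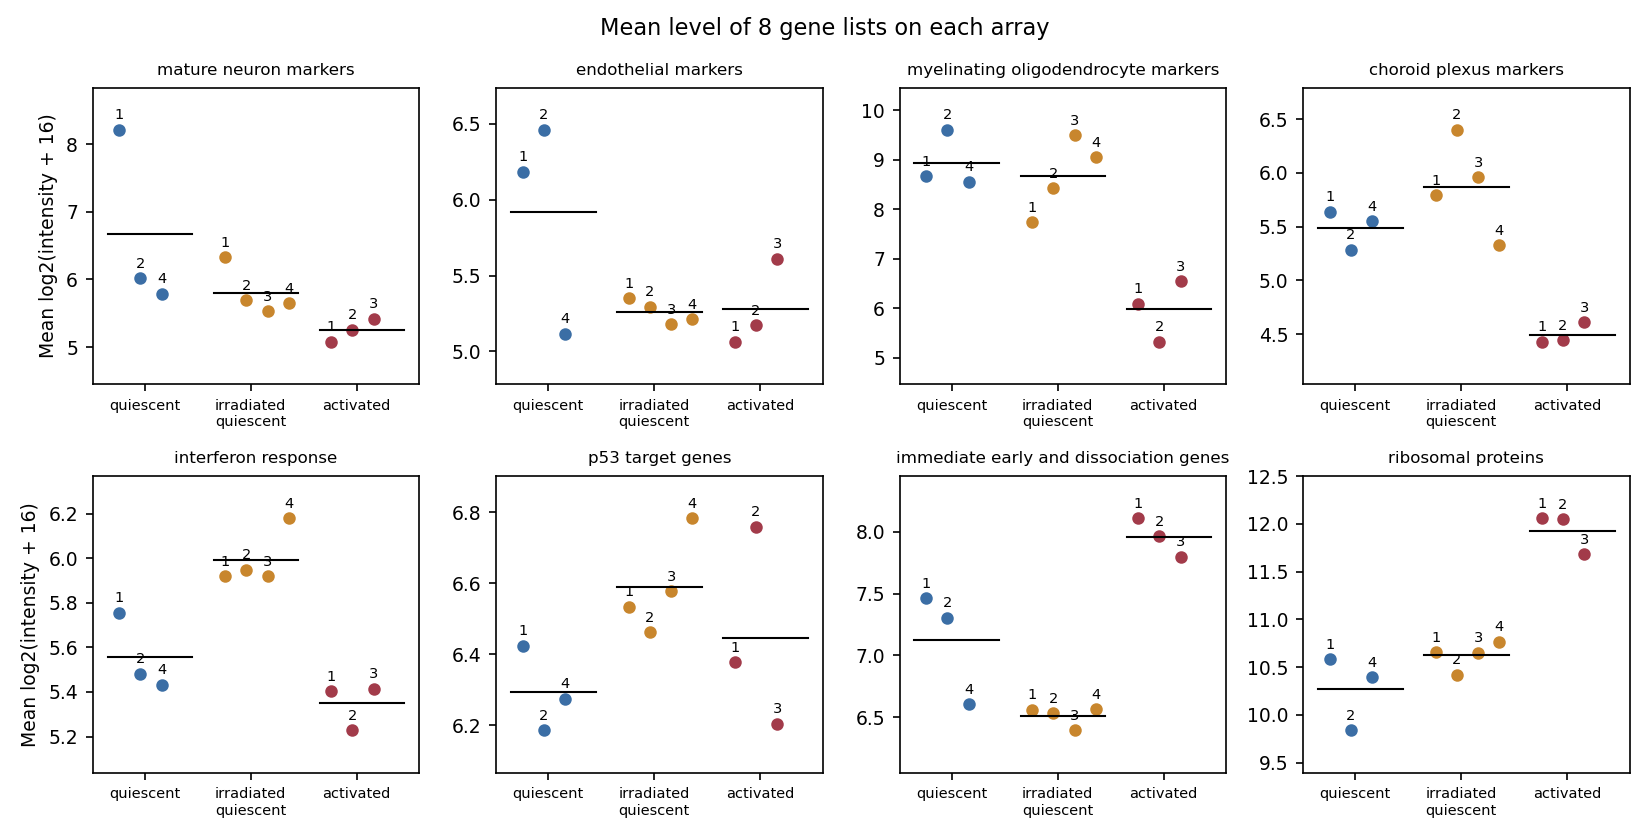
Mean log2(intensity + 16) of 8 gene lists on each array, by group, with replicate numbers beside the points and lines at the group means. Quiescent replicate 1 stands apart in mature neuron markers, quiescent replicates 1 and 2 in endothelial markers, and irradiated replicate 4 is the highest in the interferon response.

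Whether irradiated quiescent cells lay nearer to the activated state than unirradiated ones was tested along the axis from quiescent to activated cells. With the quiescent arrays divided so that the 2 differences shared none, the slope of the irradiated difference on the activated difference was -0.00733 over all genes, where 0 is no shift and 1 is the activated profile. Over the 6 divisions it ranged from -0.0222 to 0.00827. The mean score of irradiated and quiescent arrays on the axis differed by -0.00733 (exact permutation test, two-sided, p = 0.743 over 35 splits; the smallest p this design allows is 0.0286). Without quiescent replicate 4 the slope was 0.0166 (p = 0.733, exact permutation test). Over the 1094 genes called between activated and quiescent cells the slope was 0.0447 (p = 0.0286, exact permutation test), in the other direction, but these genes were chosen with the same quiescent arrays that were then scored. When they were chosen without the scored quiescent array, an alternative added after seeing the data, the slope was -0.0133 (p = 0.143, exact permutation test). Without the genes of the S phase and mitosis lists the slope was -0.00629.

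Both genes called after irradiation were also called in activated cells, in the same direction. Mrpl4 was higher in activated than in quiescent cells by 2.18 ± 0.29 and Mgat4a lower by a log2 difference of -3.53 ± 0.23. Independent lists of these sizes give 0.0289 shared genes in the higher direction and 0.0312 in the lower. An unchanged irradiated group was also simulated around the means of the real quiescent arrays. The overlap was then 0.1 genes on average over 50 runs and 1 at most. Drawn this way, the noise of the quiescent means drops out of the irradiated difference. How many shared genes the common quiescent arrays alone would give beside the real activated difference was therefore not measured. Over all genes the log2 differences of the 2 comparisons correlated at 0.26 with the shared quiescent arrays, against 0.53 for simulated groups without any effect. The covariance was 0.249 against 0.215 simulated, a difference of 0.0340, and it was -0.0101 when the quiescent arrays were divided.

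Activated cells were compared with irradiated quiescent cells as well. The same processes led. Of the 52 mitosis genes 48 rose (adjusted p = 6.76e-79), and of the 41 S phase genes 26 rose (adjusted p = 3.47e-34), with 50 and 34 higher adjusted over the list alone. Ube2c and Mki67 rose by 8.68 and 8.51, the ribonucleotide reductase gene Rrm2 by 7.45, Mcm6 by 7.20 and Insm1, a factor of neurogenic progenitors, by 7.63. Ttr (-9.32), Lcat (-6.67), Mfap3l (-6.54), the chemokine gene Cxcl14 (-6.48), Gdf10 (-6.40), the myelin glycoprotein gene Omg (-6.37), the sialyltransferase gene St6galnac5 (-6.26) and Septin4 (-6.09) fell most. Over all genes 1288 passed, 619 higher and 669 lower in activated cells. Of these, 442 were also higher and 478 also lower against unirradiated quiescent cells, and none lay in opposite directions. Both comparisons use the same activated arrays, so these shared calls are not an independent test, and how many the sharing alone would give was not measured.

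Of the other lists, activated stem cell and transit amplifying markers (17 of 36 higher, 1 lower; 22 and 1 adjusted over the list alone) and neuroblast markers (8 of 30 higher, 1 lower; 12 and 2 over the list alone) were called, the latter now also with an estimated correlation. So were homologous recombination and Fanconi genes (8 of 30 higher, 12 over the list alone), end joining and damage sensing genes (4 of 21, 5 over the list alone), ribosomal proteins (17 of 41, 30 over the list alone), ribosome biogenesis (8 of 41, 11 over the list alone) and proteasome and chaperones (3 of 34, 4 over the list alone). Immediate early and dissociation genes were called with both correlations, with 9 of 26 higher and 1 lower (13 and 1 over the list alone), and Fos rose from 58.0 ± 19.6 to 4931 ± 746 (log2 difference 6.09 ± 0.46). The lists called lower were astroglial and quiescent stem cell markers (34 of 42, 37 over the list alone; Fgfr3 at -4.17), cell adhesion and extracellular matrix (22 of 71; 29 with 1 higher over the list alone), fatty acid oxidation (12 of 32 with 1 higher, 15 and 1 over the list alone) and cholesterol synthesis (3 of 20, 10 over the list alone). Glycolysis (6 of 22; 10 with 1 higher over the list alone) and lysosome and autophagy (12 of 30, 19 over the list alone; Tpp1 at -2.90) were also lower. Myelinating oligodendrocyte markers were called lower (6 of 18, 12 over the list alone; adjusted p = 0.0968 with an estimated correlation), with Gpr37 at -4.29. Choroid plexus markers were called lower as well (adjusted p = 0.0238; adjusted p = 0.172 with an estimated correlation), where Ttr alone passed while Calml4 and Clic6 did not, and the call was lost without irradiated replicate 3 (adjusted p = 0.0550) or activated replicate 1 (0.0581).

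Mature neuron markers (adjusted p = 0.395), endothelial markers (0.969) and the interferon response (0.0527) were not called between activated and irradiated cells. Egfr passed in this comparison, at 2.76 ± 0.60 (adjusted p = 0.0346), and so did Dcx, at 4.16 ± 0.74 (adjusted p = 0.0150), Nes, at 3.01 ± 0.25, Cd24a (adjusted p = 2.76e-04) and, in the lower direction, Slc1a3 (adjusted p = 9.74e-04). Gfap, Prom1, Cdkn1a, Sox2 and Fut4 did not. The Egfr call was lost without any one of 7 arrays (highest adjusted p 0.112, without activated replicate 3), and the Dcx call without activated replicate 1 or 2 (highest 0.0573). Of the 18 lists called, 16 were also called with an estimated correlation, all but the oligodendrocyte and choroid plexus lists. The adjusted p of these 16 in camera then ran from 1.34e-04 (S phase and replication) to 0.0318 (glycolysis).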

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

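The tests of other splits of the arrays were chosen after the results they bear on had been seen, and the test of probe sets of the same gene before its result was seen. In the group of 4 irradiated arrays, 72 sets of values (genes, list means and the axis score) were checked for an array standing apart from the rest, by the gap to its nearest neighbour as a share of the range (Dixon ratio). Chance gives about 1 in 20, and 4 were found. For Egfr the ratio was 0.882, with irradiated replicate 2 at 219 and the others between 790 and 935. For Ndufa9 it was 0.883, with replicate 1 at 1678 and the others between 906 and 974. For Hspa1a it was 1, with replicate 4 at 12 and the others at 6, all close to the lower limit. For the mean of the interferon response list it was 0.891, with replicate 4 at 6.18 and the others between 5.92 and 5.95 (log2).

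The interferon list after irradiation was weighed further because it was the only list called there with both correlations when adjusted over all 3 comparisons. Adjusted within this comparison, 0 lists were called with an estimated correlation (interferon p = 0.0118 before adjustment). Among the 35 splits of the 7 quiescent and irradiated arrays into 3 and 4, 2, the real one included, gave the list a p this small (0.00216 before adjustment), the lowest of the others being 3.07e-04, so chance cannot be excluded for this list. In that other split the list was lower rather than higher, and in the higher direction only the real split reached this p, a direction not fixed in advance. Set against the whole family, the real split called 8 of the 34 lists (adjusted within the comparison), the highest other split called 6, and 1 of 35 splits called as many, so chance alone is an unlikely source of that number. Both results rest on the same 7 arrays, and none of the 8 calls held with an estimated correlation under this adjustment. The effect of irradiation on interferon genes, the explanation the design offers, stays open, as does a response limited to some samples, since replicate 4 stood apart.

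Few genes passed between irradiated and quiescent arrays. The real split called 2 genes and 18 of the 35 splits called as many, up to 17, so chance can account for the 2. For noise of single transcripts in the low-input amplification, deviations from the group mean of 2 probe sets of a gene, both bright, correlated at 0.165 over the 7 quiescent-sort arrays (95% bootstrap interval over genes 0.142 to 0.186, 2867 genes). The value on the activated arrays was 0.189. A transcript lost in amplification would move both probe sets, as would a true difference between samples, so a low correlation does not tell amplification noise from noise of single probe sets. Between 1084 and 1286 genes were at most 10 on one and at least 100 on another of 3 arrays in quiescent and irradiated groups, against 768 in the activated group. Amplification noise stays open, as does a small or absent effect of irradiation at 48 h.

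Against activated cells the picture differed. The real split of activated and irradiated arrays called 1288 genes and the highest of the other 34 called 81. As 1 of 35 splits called as many, the smallest share this design allows, chance alone is an unlikely source. Between activated and quiescent arrays the real split called 1094 genes and the highest other 204, but 10 splits (1 as large) are too few for a share under 0.05.

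Probe sets without a single gene name, which no comparison above uses, changed as well. Of 10092 such probe sets, 154 were called between activated and quiescent arrays (111 higher, 43 lower) and 150 between activated and irradiated arrays (103 higher, 47 lower). Between irradiated and quiescent arrays limma called 0 of them.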

How the results depend on the processing

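The activated against quiescent count (1094) was 519 at an adjusted p under 0.01, 680 with only the 2 groups in the fit (fewer arrays estimate the spread) and 1895 over every probe set (34945 tested); over the other settings without a left-out array it stayed between 1064 and 1465, and without each array in turn between 773 and 1036. For activated against irradiated cells (1288) it was 632, 1002 and 2241, otherwise 1253 to 1751, and 922 to 1218 without each array. The irradiated against quiescent count (2) was 1 at 0.01, under quantile normalization, with trend and robust moderation and with array weights, 0 with only the 2 groups, 4 with a pseudocount of 1, 7 over every probe set and 0 to 44 without each array; the cause was not tested. The shared genes fell from 2 to 1 at 0.01. Replicate numbers showed no sign of pairing the arrays: same-number arrays deviated from their group means with correlations of -0.0288 to 0.0211, like other pairs (-0.0296 to 0.0375). A weak pairing could be missed this way. With the replicate number as a block the 3 counts were 444, 675 and 0, and the axis slope turned to 0.0817 (p = 0.0286, exact permutation test), for a reason that was not tested. Over genes called between activated and quiescent cells the slope was 0.0447; in other settings it stayed between -0.0133 and -0.00242, and between -0.0316 and 0.0166 without each array, always with p of at least 0.143. Of 597 values of lists in other settings, 572 kept their side of the threshold, 24 lost a call, all but 1 of them with an estimated correlation or fry, and 1 gained it; of 460 with an array left out, 449 kept it and 11 lost it. Of 2086 values of named genes 2015 kept it, 59 lost and 12 gained a call, and of 1910 with an array left out 1820, 81 and 9; none reversed. Averaging probe sets ended the calls of Msmo1, Hspa9, Cct6a, Ccn1, Mgat4a, Nop16 and Syt1 in at least 1 comparison. With only the 2 groups in the fit, calls of Gabrb1, Syt1, Cldn11, Parp2, Dhcr7, Hmgcs1, Hspa9, Cct6a, Mrpl4, Mgat4a, Psmb2 and Egfr were lost, and without the dimmest 50% of genes those of Glul, Ldhb, Hmgcs1, Hspa9, Npm1 and Mrpl4. Signal near the lower limit sets what can be seen: fold changes of genes at that limit in one group are understated.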

Other observations

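Of the tests in this part, the gene families, the oligodendrocyte test and the count of heat shock genes were chosen after the results they bear on had been seen. Genes named as solute carriers or cytochromes P450 were called lower in activated cells more often than genes at large. Genes were grouped by the letters that start their symbol, after the data were examined, and 167 groups with at least 10 members above the lower limit on some array were tested in both directions among 12418 genes (one-sided Fisher's exact test, Benjamini-Hochberg over 334 tests). Of 236 genes whose symbol starts with Slc, 29 (12.3%) fell against 4.57% of all genes tested (adjusted p = 9.73e-05, Fisher's exact test), and none rose. They include the zinc transporter gene Slc39a12 (5509 ± 2531 in quiescent and 122 ± 85.5 in activated cells, SD, n = 3), the cystine transporter gene Slc7a11 (2534 ± 1719 and 66.7 ± 49.9), the bicarbonate transporter gene Slc4a4 (6465 ± 71.5 and 479 ± 324) and the glycine transporter gene Slc6a9 (2919 ± 956 and 108 ± 94.9). Of 16 cytochrome P450 genes 6 fell and 1 rose (adjusted p = 0.00322, Fisher's exact test), among them Cyp7b1, which hydroxylates oxysterols and steroids (1295 ± 369 and 11.7 ± 8.96), Cyp2d22 (2672 ± 241 and 61.3 ± 76.8) and Cyp2j9 (5138 ± 1590 and 234 ± 45.7). Under quantile normalization 31 Slc genes fell and none rose, and under median centring 36 fell and 1 rose. For P450 genes these counts were 6 and 7 lower, with 1 higher in each.

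Kinesin genes were called higher in activated cells more often than genes at large. Of 36 genes starting with Kif, 8 rose and 1 fell (adjusted p = 0.00579, Fisher's exact test), including Kif11, a spindle motor (17.3 ± 17.9 in quiescent and 2466 ± 114 in activated cells, SD, n = 3), and Kif22 (6 and 1193 ± 308). Each risen Kif gene but Kif4 is also a member of the fixed mitosis list. Some of the Slc genes that fell, such as Slc1a3 and Slc4a4, are in the fixed astroglial list. The other groups that passed, 5 of 8, were Rpl, Rps, Cdc and Mcm among rising genes and Acs among falling ones. They overlap the fixed lists too.

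Oligodendrocyte transcripts on the quiescent-sort arrays were weighed as a sign of RNA from other cells. The most abundant, Cnp, Mbp and Mal, stood at 9543 ± 1476, 6582 ± 1242 and 4158 ± 923 in quiescent cells, and 1 of the 18 members is also in the oligodendrocyte precursor list and none in the astroglial list. Over the 7 quiescent-sort arrays the 15 members with a mean above 100 varied together, with a mean pairwise correlation of 0.384 of their deviations from the group mean, against a median of 0.000177 over 10000 random lists of matched level, the 100th percentile. This is consistent with a share of oligodendrocyte RNA that differs between sorts, and an oligodendrocyte-like program within the sorted cells themselves, which would vary together as well, stays open. The sort would remove such cells only as far as its markers do, and those are not given in the sources used here.

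Immediate early genes were called higher in activated cells as a list, with 7 of 26 members higher and 1 lower, but not with an estimated correlation (adjusted p = 0.123 with an estimated correlation). For the members that rose, 2 explanations were weighed. The feedback gene test was chosen before its result was seen. If growth factor signalling in the activated sort were the whole cause, feedback targets of the same pathway would be higher too. The median log2 difference of Spry1, Spry2, Spry4, Dusp6, Etv4 and Etv5 was -0.7274, within their SD of 1.01, and none rose, while Dusp6 fell (log2 difference -2.81 ± 0.65, adjusted p = 0.0496 in limma). Spry1 was near the lower limit in both groups and Spry4 differed by only -0.07 ± 1.13, so the test is too weak to exclude growth factor signalling. For handling stress during dissociation and sorting, 2 of 4 heat shock genes were at least 1 log2 unit higher (Hsp90aa1 at 1.71 ± 0.31 and Dnajb1 at 1.26 ± 0.44), while Hspa1a and Hspa1b lay the other way (-1.99 ± 0.80 and -2.30 ± 1.21, neither passing). These 4 genes are themselves members of the list, and Hsp90aa1 is among the 7 that rose. Their count is therefore not independent of the rise it was weighed against. Both explanations stay open, as does a difference between the states themselves.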
